A study of Drosophila melanogaster with 2 samples.

How the data were processed

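Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster larvae at the wandering stage of the third instar, males and females together. The flies carried a transgene for Dorsal (dl), an NF-kB family transcription factor of the Toll pathway, fused to GFP. Per the labels, the immunoprecipitation used an antibody against GFP, although 1 label field gives the antibody as dl. There was 1 group with 2 biological replicates, numbered 3 and 1 in the labels, with sonicated fragments of 175 to 275 bp and of 200 to 275 bp. A control experiment is named in the labels and was not analysed here as a file of its own.

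The deposited files were region lists in 2 genome builds, dm6 and dm3. For each build there were 4 lists: 2 lists of candidate regions each called on 1 ChIP alignment against the control, 1 candidate list called on the pooled alignments, and 1 list thresholded by the irreproducible discovery rate (IDR), per the deposited description files. Nothing in the sources used here links the first 2 lists to replicate numbers 1 and 3, so they are called list A and list B. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each region carried a signal value, which the authors' caller gave as an enrichment of ChIP over control and which was not normalised between lists. The deposited lists also gave the −log10 of a q-value, whose maximum in the thresholded dm6 list, 3.54, was shared by 1715 regions, so regions were ranked by signal. Signal values are the authors' own and were used to describe, rank or filter regions within a list, and between lists only in a rank correlation. Read depth per replicate is unknown, because the files hold no read counts, and the intervals below cover counting of regions or genes only.

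Coordinates are 1-based and in dm6. Genes were taken from Ensembl release 115 (BDGP 6.54) without transposable elements and pseudogenes, and sequence from the release 6 reference assembly. All dm6 regions on the arms ended within the lengths of their chromosomes. The dm3 lists were used only for counts and for agreement between lists, since no dm3 reference was used here. Annotation and sequence tests used the chromosome arms (2L, 2R, 3L, 3R, 4, X and Y).

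Agreement between the lists was the share of the 2718 best regions of one list whose summit lay in one of the 2718 best of the other, with the same share after a shift of 5000 bp as the chance level. Summits were assigned to 1 of 7 classes in the order promoter (within 500 bp of an annotated transcription start site), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Thresholded peaks were compared with pooled candidates that did not pass by Fisher's exact test. For 19 gene lists, genes with a peak summit within 1000 bp of any start site were compared with all other protein-coding genes by Fisher's exact test. The background was the protein-coding genes with at least 1 pooled candidate in that window. Odds ratios have Woolf 95% intervals, with a continuity correction where a cell was 0. Of the listed symbols, 4 were not found in the annotation. The lists covered the Toll pathway, antimicrobial peptides and bomanins, the Imd pathway, dorsoventral targets of the embryo, the ecdysone response, salivary gland glue, fat body, hemocytes and melanization, muscle, neuronal genes, cuticle proteins, midgut digestion, Hox genes, Notch targets, JNK and JAK-STAT signalling, heat shock and stress, ribosomal proteins, clock genes, and insulin and growth.

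For 20 motifs, the share of peaks with a match on either strand within 100 bp of the summit was compared with a window of equal length 1000 bp away, on a random side, by the exact McNemar test. The dl motif was GGGWWWWCCM or GGGWWWWWCCM, where W is A or T and M is A or C, and 100 permuted forms of it served as a check of base composition. Differences in signal rank between peaks with and without a motif were tested by permutation with 100000 resamples. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over classes, lists or motifs, with a threshold of 0.05, and shares have exact Clopper-Pearson 95% intervals. Regions and genes, not animals, are the units of these tests, so the p-values describe these lists and not variation between larvae.

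The genes named are the nearest annotated gene of each of the 20 peaks of highest signal on the arms, up to 4 members per list with a promoter peak by highest signal, up to 4 members without a peak in list order for the Toll, antimicrobial and dorsoventral lists, and dl. This rule, the gene lists, the motifs and the tests were fixed before the data were examined, except the signal test of the GAGA motif. The planned signal test named only the dl motif. Alternatives were other promoter, gene and motif windows, other backgrounds, a stricter threshold at the median signal, other overlap rules, dm3, covariates, and each single list in place of the combined one. The single lists stand for leaving out a replicate whose number is not known. Alternatives that concern the GAGA motif, the logistic model without a covariate, and the flank on the other side were chosen after seeing the data.

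The tests were tested on simulated data built from the real candidates. A planted promoter effect was called in 20 of 20 simulations of 29970 candidates, and a planted gene list in 20 of 20 over 5660 genes. Candidates of the planted genes had 20 times the weight of others, so power for smaller lists or weaker effects is not shown. With no effect, 0 of 140 class tests, 0 of 200 list tests and 0 of 40 motif tests were called. There, peaks were drawn evenly from the candidates, and gene lists were random. These runs therefore do not cover the number of start sites or the clustering of genes in the real lists. The motif runs used summits of the drawn candidates, whose base composition may differ from that of the real peaks. A dl site inserted into 4.46% of 2690 windows was recovered as a difference of 4.31 percentage points. This was 1 trial on candidates drawn at random, so power for a smaller share of sites is not shown. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.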

Results

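Genomic regions recovered by ChIP of GFP-tagged Dorsal were profiled in whole larvae at the wandering stage of the third instar. Larvae at this stage leave the food before pupariation. Dorsal patterns the dorsoventral axis of the embryo and acts later in the immune response of the Toll pathway. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between peaks and background regions, and between the lists of the replicates. Read depth is unknown.

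The authors' thresholded list held 2718 regions in dm6, with a median width of 244 bp and a covered length of 582.1 kb. Of these, 2690 lay on chromosome arms and 28 on the mitochondrial genome. Peaks numbered 503 on 2L, 525 on 2R, 563 on 3L, 674 on 3R and 418 on X. Chromosome 4 held 7 peaks from 509 candidates, so that 1.38% of its candidates passed (95% interval 0.555 to 2.81%), against 8.35 to 10.1% on the other arms with candidates. Every thresholded region was in the pooled candidate list, where they were the 2718 regions of highest signal.

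The peak of highest signal on the arms lay at 3R 8316764 to 8317086, with its summit 41 bp from a start site of lncRNA:CR45215 and 400 bp from the nearest coding start site, that of Coq2, and had a signal of 2824. The next were promoter peaks of CG3253 (2R 24114216 to 24114481, signal 1698), Mic26-27 (3R 16146603 to 16146874, signal 1646), shot, which encodes a spectraplakin that links actin and microtubules (2R 13925490 to 13925720, signal 1618), and CG12299 (2L 10737197 to 10737442, signal 1332). Of the 20 peaks of highest signal, 18 were at promoters, those also including mura, Smg5, GstE12, rhea (talin), CG31522, lncRNA:CR46110 inside kay, Zasp52, sbb, lncRNA:CR42746 inside bun, CG8500, DUBAI, Gnpat and sd (scalloped). The other 2 were intronic. One lay in B4, 14331 bp from the nearest start site, that of CG33640 (2L 13513410 to 13513593, signal 889.2). The other lay in Eip74EF, an ETS factor of the ecdysone response, 14239 bp from its nearest start site (3L 17590723 to 17590991, signal 814.4). Of these 20 peaks, 16 overlapped regions among the 100 best of both list A and list B. The pooled signal that ranks them comes from the same alignments, so this overlap is partly built in.

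The lists of the replicates shared a part of their best regions. Of the 2718 best regions of list A, 1574 (57.9%, 95% interval 56.0 to 59.8%) had their summit in one of the 2718 best of list B, and in the other direction 1616 did (59.5%, 95% interval 57.6 to 61.3%). After a shift of 5000 bp, 46 did (1.69%). Of the thresholded peaks, 1584 (58.3%) had their summit in the best regions of both lists and 159 in those of neither. Among the 680 peaks of highest signal the share in both was 94.6%, and among the 680 of lowest signal it was 7.94%. Signal here is that of the pooled list, called on the same alignments as lists A and B, so the high share is partly built in. The 680 of lowest signal lie at the cut-off of the pooled list, so a low share there is partly built in too. Of all 2718 peaks, 2498 (91.9%) had their summit in a candidate of any rank in both lists. Across the 2480 arm peaks matched to a candidate in both lists, the signals had a Spearman rho of 0.58. That correlation is across regions, which are not independent replicates.

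Peaks were found at promoters more often than the candidates that did not pass. Of 2690 peaks, 1491 (55.4%, 95% interval 53.5 to 57.3%) had a summit within 500 bp of a start site, against 5839 of 27280 other candidates (21.4%). The odds ratio was 4.57 (95% interval 4.21 to 4.95, Fisher's exact test, adjusted p = 2.31e-287), and 8.13 against random positions. Introns held 29.9% of peaks and 46.4% of other candidates (odds ratio 0.493), and intergenic sequence 10.4% and 21.1% (odds ratio 0.433). Coding exons held 0.558% and 3.68% (odds ratio 0.147) and 3′ UTRs 0.818% and 5.27% (odds ratio 0.148), each with an adjusted p of 2.12e-24 or lower. The coding exon odds ratio was 0.0384 with list B alone, 0.0372 against random positions and 0.0781 at or above the median signal. 5′ UTRs held 2.08% and 1.18% (odds ratio 1.77, Fisher's exact test, adjusted p = 0.000227), a difference that did not pass with a promoter window of 1000 bp (odds ratio 1.11) and was larger against random positions (odds ratio 2.97). For other exons the difference did not pass (Fisher's exact test, adjusted p = 0.613). The median distance from summit to start site was 370.5 bp for peaks and 2113 bp for other candidates.

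**Figure D1:**
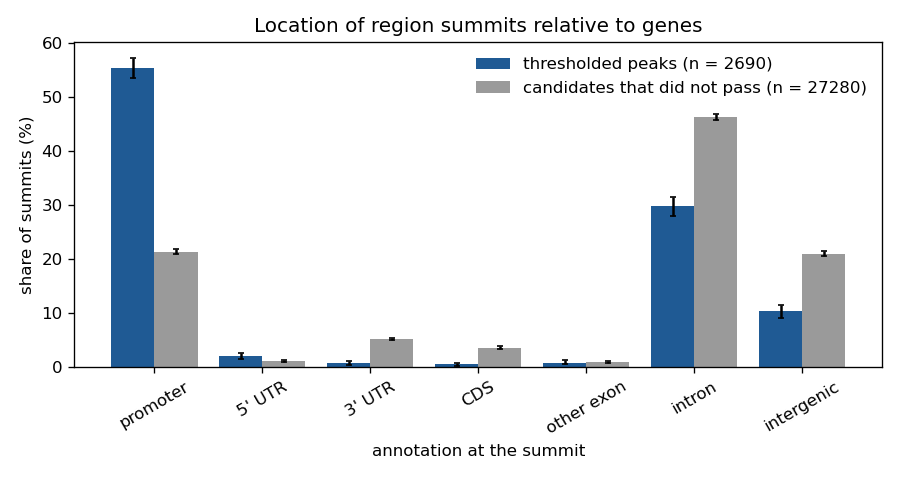
Share of region summits (%) in each of 7 annotation classes, for 2690 thresholded peaks and 27280 pooled candidates that did not pass; bars are shares and error bars exact 95% binomial intervals. Promoters hold 55.4% of peaks against 21.4% of other candidates, and introns 29.9% against 46.4%.

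Genes of the ecdysone response, the steroid signal that drives the larval to pupal transition, carried promoter peaks more often than other genes. Of 21 testable members, 19 had one (90.5%, 95% interval 69.6 to 98.8%), against 26.4% of the other 5639 genes (odds ratio 26.6, 95% interval 6.18 to 114.1, Fisher's exact test, adjusted p = 2.42e-08). The list passed under all 10 alternatives, but its odds ratio was 12.5 with list A alone and 12.2 with list B alone, 11.7 with a 500 bp window and 8.80 with peaks at or above the median signal. The strongest were at Eip74EF (3L 17619369 to 17619540, 115 bp from a start site, signal 586.5), E23 (2L 3354812 to 3354970, signal 497.1), the receptor gene EcR (2R 6132083 to 6132216, signal 432.4) and the nuclear receptor gene Hr3 (2R 10228011 to 10228158, signal 278.2).

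Genes of the Toll pathway, in which Dorsal acts, had promoter peaks at 8 of 13 testable members (61.5%, 95% interval 31.6 to 86.1%; odds ratio 4.44, 95% interval 1.45 to 13.6, Fisher's exact test, adjusted p = 0.0228). They included spz, the Toll ligand (signal 295.1), 18w (252.7), dl itself (249.3) and Dif, a second NF-kB gene beside dl (233.1). Of all 22 members, 14 had no promoter peak, among them pll, tub, PGRP-SA and PGRP-SD. These named genes had no candidate in the window and were not part of the test, in which 5 members had no peak. In the same exact test the call was lost with list A alone (odds ratio 2.04, adjusted p = 0.282) and with peaks at or above the median signal (odds ratio 3.35, adjusted p = 0.133). With a 500 bp window the odds ratio rose to 10.9. At dl (2L 17436830 to 17450364), 3 peaks lay near its start sites, at 17448540 to 17448783, 17449744 to 17449981 and 17450281 to 17450524, with signals of 99.1, 249.3 and 238.5. All 3 overlapped candidates of both lists. The gene held 0.222 candidates per kb, against a median of 0.225 over 1939 genes of similar length. That density counts candidates whether or not they passed, so it does not describe the peaks. Of the 3 candidates with a summit inside dl, 2 passed, against 8.98% of all candidates on the arms. Inside Dif, peaks nearest to lncRNA:CR44409 had signals of 361.3, 177.5 and 170.5. The cause was not tested.

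Antimicrobial peptide and bomanin genes, the effectors induced by Toll and Imd signalling, had a promoter peak at 1 of 21 testable members (4.76%, 95% interval 0.12 to 23.8%). That member was Drsl1 (3L 3335579 to 3335788), with a peak at 3L 3334888 to 3335131 (signal 159.6). The peak summit was 778 bp from the start site of Drsl1, beyond the opposite end of the gene. No testable member had a peak with a 500 bp window (0 of 13) or with the nearest start site only (0 of 21). The odds ratio in the main test was 0.137 (adjusted p = 0.0492, Fisher's exact test), with a 95% interval of 0.0184 to 1.03 that included 1. Many testable members lie in clusters, such as the bomanins from BomS1 to BomS6 at 2R 18383949 to 18390629. Neighbours can share a candidate, so these genes are not independent units, as the test assumes. The call was lost under 8 of 10 alternatives, by exact tests or a logistic model, including list A alone (odds ratio 0.305, adjusted p = 0.247) and list B alone (odds ratio 0.254, adjusted p = 0.377). It held with a 5000 bp window (odds ratio 0.227) and with the nearest start site only (odds ratio 0.0784). Of all 37 members, 36 had no promoter peak, among them Drs, Drsl2, Drsl3 and Drsl4. Drs and Drsl2 had no candidate in the window and were not part of the test, in which 20 members had no peak. AttA and AttB, and CecA1 and CecA2, are near-identical copies, and their values are uncertain.

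The list of dorsoventral targets of the embryo had promoter peaks at 11 of 26 testable members (42.3%, 95% interval 23.4 to 63.1%). Its members were not separated into direct targets of Dorsal and other genes. The difference from genes outside the list did not pass (odds ratio 2.03, 95% interval 0.931 to 4.43, Fisher's exact test, adjusted p = 0.133). The strongest were at ush (743.7), brk (341.7), Mef2 (209.1) and dpp (186.0). Of all 31 members, 20 had none, among them the ventral genes twi and sna, and rho and vn. In the exact test the list passed with list A alone (odds ratio 3.51, adjusted p = 0.0315) and with all coding genes as background (odds ratio 4.58, adjusted p = 0.000651). In a logistic model with a GAGA sequence near the start sites as covariate its odds ratio fell to 1.20 (95% interval 0.512 to 2.83).

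Of the 19 lists, 8 had promoter peaks more often than other genes, 1 less often, and 10 did not pass. The other lists that were higher were JNK and JAK-STAT signalling (11 of 15, odds ratio 7.64, Fisher's exact test, adjusted p = 0.00196; dome, kay, puc and msn), Imd (10 of 16, odds ratio 4.63; imd, Rel, Tab2 and Tak1), insulin and growth (11 of 18, odds ratio 4.36; sd, InR, Thor and ds), hemocytes and melanization (9 of 14, odds ratio 4.99; ush, MP1, srp and Spn28Dc), Hox genes (6 of 8, odds ratio 8.31; Dfd, lab, Ubx and Abd-B) and heat shock and stress (10 of 18, odds ratio 3.47; Hsp22 and CG4456, which share 1 peak, Thor and Hsc70-3). Lists that did not pass were Notch targets (7 of 14; E(spl)m3-HLH and hry), clock genes (3 of 6; sgg, vri and Pdp1), neuronal genes (4 of 12; elav and Syx1A), salivary gland glue (2 of 6; CrebA and fkh), fat body (3 of 10; srp, bmm and Lsd-2), muscle (2 of 12; Tm1 and Mef2), midgut digestion (2 of 14; lab and GATAe), ribosomal proteins (8 of 43; RpS20 and RpL10Ab) and cuticle proteins (0 of 5). Several genes belonged to more than 1 list, and 261 of the 1758 peaks within 1000 bp of a coding start site counted for more than 1 gene. Neighbouring members of gene clusters, such as the E(spl) and bomanin genes, are also not independent units.

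Most of these calls depended on a setting. With list A alone, 2 of the 9 calls held and the dorsoventral list was gained. With list B alone, 6 held and Notch targets were gained, and with peaks at or above the median signal 3 held. In a logistic model, 8 lists passed without a covariate and 5 with a GAGA sequence near the start sites as covariate, both chosen after the data were seen. The antimicrobial list was already lost without the covariate, at the same odds ratio of 0.137. From the model without to the model with the covariate, the odds ratio went from 4.36 (95% interval 1.69 to 11.3) to 2.51 (0.886 to 7.12) for insulin and growth genes and from 8.31 (1.68 to 41.2) to 3.32 (0.614 to 17.9) for Hox genes, with both calls lost. For heat shock genes it hardly moved, from 3.47 (1.37 to 8.80) to 3.40 (1.23 to 9.40), and the interval still excluded 1, but the adjusted p rose from 0.0215 to 0.0549. Insulin and growth genes passed under the other 9 alternatives, with odds ratios of 9.52 on list A alone, 16.7 on list B alone and 7.64 with all coding genes as background. The JNK and JAK-STAT call was lost on list A alone (2.92, exact test, adjusted p = 0.0816), and the odds ratio was 3.84 on list B alone, 4.71 at the median signal and 4.92 with the GAGA covariate. With all coding genes as background the odds ratio rose to 6.94 for Imd, 16.6 for Hox and 5.55 for heat shock genes, and for the last it was 8.02 with a 5000 bp window.

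Imd genes lost their call in exact tests on list A alone (2.55, adjusted p = 0.158), on list B alone (1.91, adjusted p = 0.377), with a 5000 bp window (2.86, adjusted p = 0.0685) and at the median signal (1.79, adjusted p = 0.440). In a logistic model with the number of start sites as covariate their odds ratio was 3.30 with a 95% interval of 1.16 to 9.37, which excluded 1, and the adjusted p was 0.0507. Hemocyte genes lost it in exact tests on list A alone (2.92, adjusted p = 0.140), with windows of 500 bp (3.18, adjusted p = 0.125) and 5000 bp (1.91, adjusted p = 0.237) and at the median signal (2.98, adjusted p = 0.133). Heat shock genes lost it in exact tests on list A alone (2.92, adjusted p = 0.0816), with a 500 bp window (2.18, adjusted p = 0.189) and at the median signal (2.68, adjusted p = 0.133). Hox genes lost it in exact tests on list A alone (4.86, adjusted p = 0.0816), on list B alone (3.83, adjusted p = 0.134) and at the median signal (3.21, adjusted p = 0.249).

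Of the lists that did not pass, Notch targets passed as higher in exact tests on list B alone (3.83, adjusted p = 0.0238), with a 5000 bp window (7.45, adjusted p = 0.00061) and with all coding genes as background (5.82, adjusted p = 0.00257). In a logistic model with the number of start sites as covariate they also passed, at an odds ratio of 3.75, while at the median signal it was 1.46 and did not pass. Cuticle proteins passed as lower with a 5000 bp window, where 0 of 19 testable members had a peak (0.0583, exact test, adjusted p = 0.00543).

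**Figure D2:**
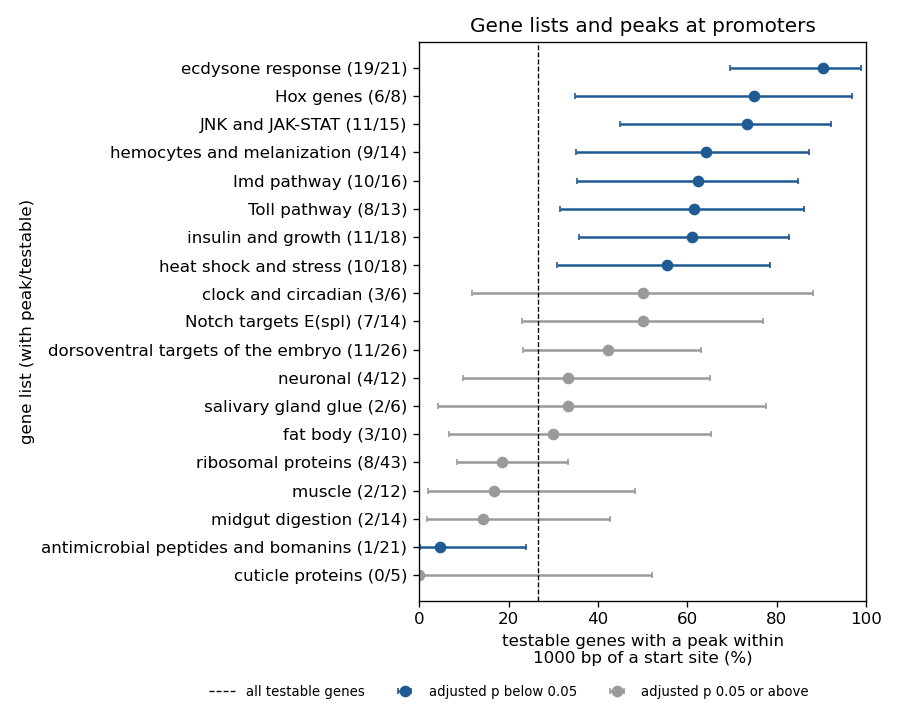
Share of testable genes (%) with a peak within 1000 bp of a start site, for 19 gene lists; points are shares, bars exact 95% binomial intervals, and the dashed line the share over all 5660 testable genes (26.6%). The ecdysone response is highest at 90.5%, and antimicrobial peptides are at 4.76%.

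No difference in the dl motif between summits and flanks was detectable. It was present within 100 bp of 41 of 2690 summits (1.52%, 95% interval 1.10 to 2.06%) and in 43 flanking windows (1.60%), a difference of -0.0743 percentage points (95% interval -0.742 to 0.593, exact McNemar test, adjusted p = 0.992). Of 100 permuted forms of the motif, 69 had an odds ratio at or above that of dl (0.953). A wider kappaB consensus was less frequent at summits, at 8.10% against 10.7% (odds ratio 0.725, exact McNemar test, adjusted p = 0.00354). The GAGA motif, GAGAGAG, which is bound by GAGA factor and other proteins, was present at 1182 summits (43.9%, 95% interval 42.1 to 45.8%) and in 136 flanks (5.06%), an odds ratio of 16.6 (95% interval 12.98 to 21.3, exact McNemar test, adjusted p = 6.89e-244). That odds ratio was 27.2 and 7.59 with windows of 50 and 250 bp, 7.97 against candidates of the same GC content and 26.0 at or above the median signal. The CTCF motif (11.9% against 7.84%, odds ratio 1.58) and the Myc E-box (3.64% against 2.16%, odds ratio 1.71) were also higher at summits. The Stat92E motif (3.94% against 6.02%, odds ratio 0.641) and the FoxO motif (6.47% against 9.48%, odds ratio 0.655) were lower. Base composition also differed between summits and flanks: AAAAAAA (odds ratio 0.575) and ATATATA (0.475) were lower and CGCGCGC (2.74) higher, while GGGGGGG (1.09) did not pass. Only the dl and GAGA motifs were compared at matched GC content, so composition was not separated from the other differences. The other 13 motifs, those of Zelda, the Twist E-box and DREF among them, did not pass. For some of them matches were too few to decide. The ecdysone receptor motif was found at 1 summit and in 1 flank, and the heat shock factor motif at 2 summits and in 6 flanks.

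**Figure D3:**
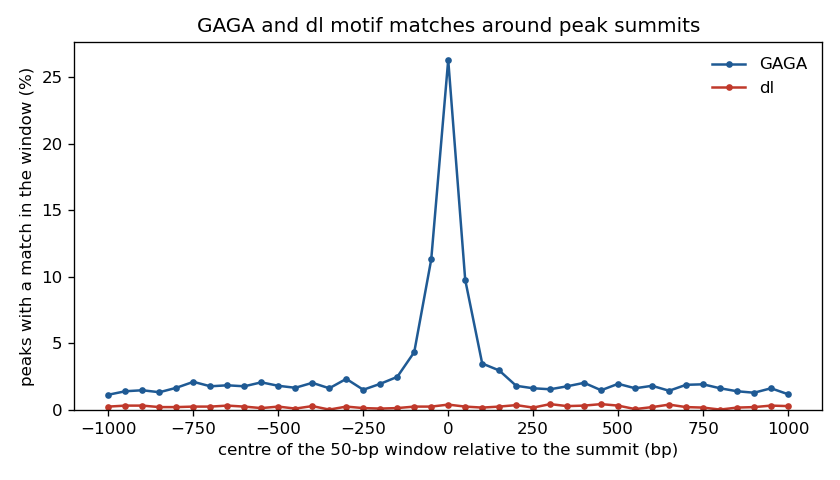
Share of 2690 peaks (%) with a GAGA or dl motif match in 50-bp windows, by the position of the window centre relative to the summit (bp). GAGA reaches 26.3% at the summit and 1.15% at the window 1000 bp to the left, while dl is at 0.409% at the summit.

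The motifs differed in how they went with peak strength. The signal test was planned for the dl motif only, and the GAGA motif was added to it. Peaks with the GAGA motif ranked 16.0 percentile points higher in signal than peaks without it (permutation test, p = 1e-05, the smallest these resamples can give). The share with the motif was 26.6%, 38.1%, 48.1% and 63.0% from the lowest to the highest quartile of signal. Among the 20 peaks of highest signal, which are few, 8 had the motif, a lower share than in the highest quartile as a whole. Peaks with the dl motif had a mean percentile of 37.6 against 50.2 without it, a difference of -12.6 (permutation test, p = 0.00564), which was -7.71 with a motif window of 250 bp (permutation test, p = 0.0196). The dl share was 2.67% in the lowest quartile (95% interval 1.59 to 4.19%) and 0.594% in the highest (95% interval 0.162 to 1.51%), which rest on 18 and 4 peaks. In promoter peaks alone the dl difference did not pass (-11.1, permutation test, p = 0.108).

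**Figure D4:**
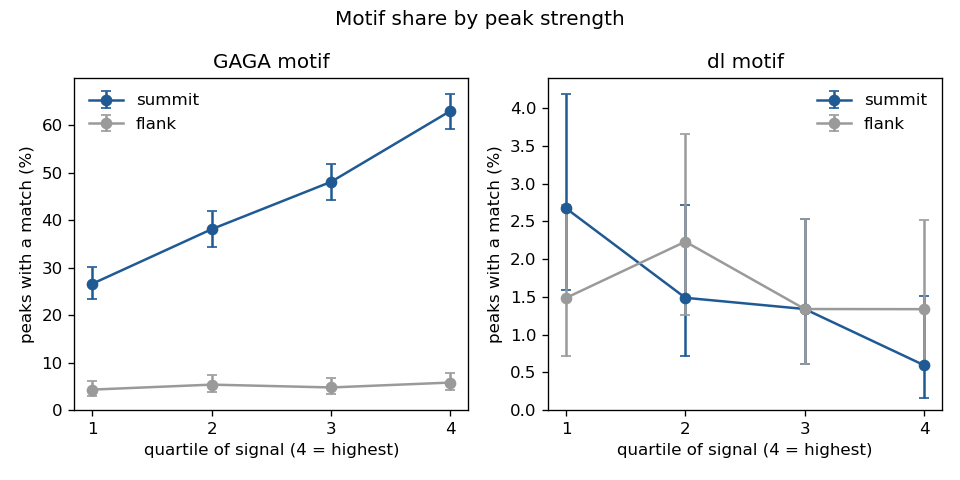
Share of peaks (%) with a GAGA (left) or dl (right) motif match at the summit and in the flanking window, by quartile of signal; bars are exact 95% binomial intervals. GAGA at summits goes from 26.6% to 63.0%, and dl from 2.67% to 0.594%.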

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

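The tests in this part were chosen after the results were seen. In data outside the peaks on chromosome arms, 28 thresholded dm6 regions lay on the mitochondrial genome, and they included the region of highest signal (4340). In the dm3 list 1 region did, with a signal of 170.8, while 11 regions lay on the unplaced sequence chrUextra. A difference in the amount of mitochondrial DNA between ChIP and control would raise the whole molecule. Summits lay in 15 of 20 bins of 1 kb (75%), and the last was at 14503 of 19524 bp. Every bin up to that last summit held a summit, and all bins without one lay beyond it. The test asked for 90% or more to count for this explanation and under 50% to count against it. By that rule it stays open, but the 75% depends on counting the sequence beyond the last summit. Reads with more than 1 match in dm3 could lower the dm3 count. The rule asked for at least as many regions on chrUextra as the 27 mitochondrial regions lost to count for this, and for none to count against it. With 11 regions this stays open too. The aligner is not given, so how such reads were placed is unknown and the count cannot decide. The dm3 sequence was not used here. No biological explanation was tested.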

How the results depend on the processing

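The alternatives with the GAGA motif, the GAGA covariate, the logistic model without a covariate and the other flank were chosen after seeing the data. Direction and side of the threshold held under all alternatives run for the promoter location (odds ratio 3.43 to 8.13), the ecdysone list (8.80 to 32.6), the GAGA motif (7.59 to 27.2) and its relation to signal. The peak count was 1359 at or above the median signal, by construction. Agreement of list A with list B was 59.8% with 50% overlap, 66.3% with N halved and 46.2% with N doubled. The number of gene lists that passed was 3 at or above the median signal and 3 to 7 with single lists, of which 2 and 6 were among the 9 of the main test. In logistic models it was 8 without a covariate, 8 with start sites and 5 with GAGA, against 9 in the exact tests. The Toll list lost its call at or above the median signal (3.35), with single lists ranged from 2.04 to 4.32, and was highest with a 500 bp window (10.9). The antimicrobial list lost its call with a window of 500 bp (0.100), all coding genes as background (0.230), the start site covariate (0.214), the median signal (0.266), the GAGA covariate (0.256) and the logistic model without a covariate (0.137), and ranged from 0.254 to 0.305 with single lists. The dorsoventral list passed with all coding genes as background (4.58), ranged from 2.25 to 3.51 with single lists, and was lower with the start site covariate (1.77) and the GAGA covariate (1.20). The dl motif passed only with the wider consensus, and lower at summits (0.725). Its odds ratio, not past the threshold, turned above 1 with GC-matched candidates (1.16), the other flank (1.21) and peaks without GAGA (1.17), and ranged from 0.684 to 1.08 with single lists. Its relation to signal did not pass in promoter peaks (-11.1), and was -16.0 with a 50 bp and -7.71 with a 250 bp window. Values that never passed also changed direction: other exons with a 250 bp window (1.11), random positions (1.13) and single lists (0.868 to 1.05), glue genes at 5000 bp (0.652), fat body at 500 bp (0.339) and with start sites (0.957), muscle at the median signal (1.07), neuronal genes at 500 bp (0.905), 5000 bp (0.815), with start sites (0.964) and with GAGA (0.755), and ribosomal proteins at 5000 bp (1.27) and with single lists (0.574 to 1.02). The cause was not tested for any of these. Read depth is unknown, so its part in the agreement between lists could not be tested.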

Other observations

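The tests of promoter location and of simple repeats in this part were chosen after the result was seen, as was the search for sequence words. GAGA matches were spread over the locations: 44.3% of promoter peaks, 46.5% of intronic peaks and 34.4% of intergenic peaks had one. In the 1508 peaks without a match, 7863 words of 7 bp were tested. At the summits of odd-ranked peaks 248 words were more frequent than in their flanks and 277 less frequent, and 168 of the 248 also passed in the even-ranked peaks. Of these 168, 131 (78.0%) held AGAG, GAGA, GAGC, GCGA or AGCG on either strand, against 997 (12.7%) of all tested words. These cores were picked from the same 168 words, so the contrast describes them and is not a test. A further 11 held a CA repeat, and 26 held neither.

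The GAGA motif was frequent at summits, where the dl motif was not above its flanks. Base composition as the whole source is argued against by candidates of the same GC content that did not pass, of which 8.96% had the motif, an odds ratio of 7.97 (95% interval 7.06 to 8.99). Promoter location is argued against by peaks outside promoters, where the odds ratio was 14.9. Simple repeats in general are argued against because the highest odds ratio of 5 other repeats was 2.77 (CACACAC, 95% interval 2.35 to 3.27). A candidate explanation that stays open is recovery of open chromatin by the antibody or the sonication whatever the tagged protein binds, which needs a ChIP without the tag or of another factor, not analysed here. Recruitment of Dorsal through other proteins, a hypothesis, cannot be separated from it with 1 group.

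Ecdysone genes may carry promoter peaks for reasons of gene structure. With the number of start sites as a covariate the odds ratio was 20.5 (95% interval 4.62 to 90.6), and with a GAGA match within 500 bp of a start site it was 18.05 (95% interval 3.96 to 82.3), so neither accounts for the whole difference. Expression or accessibility of these genes at this stage was not measured in these files and stays open. No biological explanation was tested.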
